A study of Homo sapiens with 2 samples.

How the data were processed

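RNA of 2 human hepatocellular carcinoma lines, Huh7 and HepG2, was compared between cells infected with lentiviral THOC5 shRNA and cells infected with control shRNA, 5 days after infection. Per the labels, total RNA was copied into labelled cRNA with an Agilent two-colour kit, the control shRNA RNA in Cy3 and the THOC5 shRNA RNA in Cy5, on 1 array per line. Both arrays have the same dye orientation, and no dye swap or replicate array was analysed here. The groups are therefore the 2 lines with 1 array each. Per the file headers, both arrays are separate fields of one slide and one scan, so slide and scan do not differ between them, and the slide as a block was not fitted.

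The deposited scanner tables hold spot intensities on a linear scale, the mean signal and the local background median of each channel, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, the same software subtracted background with spatial detrending, normalized the dyes by linear and LOWESS steps, and wrote processed signals and their log10 ratio of Cy5 over Cy3 for each spot. The deposited scanner tables also hold flags of 0 or 1, scored here as other values, for signal well above background, saturation and outliers among the spots of a probe. The authors' series matrix holds 1 value per probe with a median of 0.00 in both columns. Its scale and direction were found from the scanner values. The matrix correlated across probes with the mean log10 ratio of the same array at 0.974 (Huh7) and 0.966 (HepG2), with slopes of 0.933 and 0.922, so it is a log10 ratio of Cy5 over Cy3; how the spots of a probe were combined stays unknown.

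Each array has 181560 spots, of which 170635 belong to gene probes printed 5 times each. Outlier flags removed 16.4% of gene spots in Huh7 and 16.0% in HepG2. Cy3 was well above background in 64.4% and 66.9% of spots, Cy5 in 69.7% and 68.7%, and 0 and 4 probes were saturated. The number of arrays limits the precision of every value. Accessions on the array were matched without versions to a RefSeq gene table of GRCh38.p14, used for names only; 26242 of 34127 gene probes matched 1 symbol, 7885 matched none and kept no gene name, and 20027 genes had a probe, 5129 of them more than 1. Of the unnamed probes, 90 of 4169 measured in Huh7 and 70 of 4159 in HepG2 passed the 2-fold rule and are not described further.

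Background was corrected with normexp (offset 50) and ratios were normalized within each array by loess with control and filler spots at weight 0, using limma 3.58.1 in R 4.3.3. Outlier spots were left out and the remaining spots of a probe averaged, and a gene is represented by its brightest probe over both arrays. A gene counted as measured if its probe was well above background in at least 1 channel, in at least 50% of its spots. Where a probe was not well above background in 1 channel, a fold is given as a bound, the brighter channel against the higher of the dim channel's own value and the lowest signal well above background, after loess and Aquantile; such bounds are open to dye bias. The offset draws ratios of dim probes toward 0. With 1 array per line, genes were counted by a fixed size rule, a log2 ratio of −1 or less or 1 or more, without a p-value. Over both lines, lmFit and eBayes tested the mean log2 ratio against 0 with the 2 lines as replicates. The test had 1 residual degree of freedom before moderation, with Benjamini-Hochberg adjustment at 0.05. Its p-values set the mean against the moderated spread between lines, which holds both line differences and array noise.

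The 29 gene lists, the rule for named genes, the limma test and most alternatives were fixed before the data were examined. Named genes are the THO and TREX members, the 10 lowest and 10 highest genes per line, the 12 lowest and 12 highest over both lines by the smaller absolute log2 ratio, 5 genes per direction with opposite ratios, all well above background in both channels and unsaturated, and the members of each list with the largest ratios. Some genes that met this rule, and the outcome for 1 gene in a test, are not reported here. The lists covered mRNA export, liver products, transcription factors and metabolism, liver cancer markers, cell cycle, replication, histones, p53, apoptosis, interferon, NF-kB, unfolded protein, heat shock, metallothionein, NRF2, cholesterol, fatty acid, glycolysis, immediate early, ribosomal, respiratory, vesicle, epithelial, mesenchymal, bile duct, endothelial, leukocyte and reference genes. Vesicle genes and TMBIM4 were included knowing the study. Of 621 list entries, 11 had no probe matched to them. The median of each list was placed among 10000 random lists of the same size matched on brightness in 20 bins, as a description of these arrays.

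On simulated Huh7 spots (22299 probes measured on both arrays), probes set to −1 and 1 were found at medians of −0.87 and 0.86, so 2 and 1 of 50 passed the size rule; probes set to −2 and 2 were found at −1.53 and 1.77, and 43 and 50 of 50 passed, with 0 of 22099 unchanged probes. The limma step over both lines on 22299 probes, with a constant spread, called 66 of 66 probes set to 1, 67 of 67 set to 2 and 67 of 67 set to 3, with 9 false calls among 22099 unchanged probes. With the spread drawn from its estimated distribution, it called 0 of 66 probes set to 1, 41 of 67 set to 2 and 60 of 67 set to 3, with 5 false calls. With the spread resampled from the observed differences between lines, it called 0 at every size and 0 of the unchanged probes. For the lists, 49 of 1000 random lists of 20 probes fell outside the central 95%, and 998 of 1000 lists shifted by 0.5 were above it. Alternatives covered background correction, its offset, normalization, the scanner software's ratios, the series matrix, scaling between arrays, filters on dim probes, outlier spots, several probes per gene, the size rule and the moderation; centring on the E1A spike-in RNAs, leaving out genes with disagreeing probes and comparing probes within genes were added after seeing the data. Tables and figures were made with pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.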

Results

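Gene expression was measured after depletion of THOC5, a subunit of the THO complex, which joins other proteins in the TREX complex to couple transcription with the export of mRNA from the nucleus. Huh7 and HepG2 are cell lines from human liver cancer, and both were infected with a lentivirus carrying a short hairpin RNA (shRNA) against THOC5 or with a control shRNA. Total RNA was taken 5 days after infection. For each line, Cy5-labelled RNA of the THOC5 shRNA cells and Cy3-labelled RNA of the control shRNA cells were hybridised together on 1 two-colour Agilent array, so the data hold 2 arrays and no replicate within a line. Values are log2 ratios of THOC5 shRNA over control shRNA, negative when the transcript was lower in depleted cells, and each SD given is over the replicate spots of a probe on 1 array. The median spot SD was 0.05 in both lines, and it holds technical noise only. Median spot signals before background correction were 143 (Cy3) and 312 (Cy5) on the Huh7 array and 135 and 280 on the HepG2 array.

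The first comparison asked how far the target and its partners in mRNA export were lowered. THOC5 was lower in both lines. Its log2 ratio was −1.52 in Huh7 (SD 0.05 over 5 spots), which leaves 34.9% of the control level. In HepG2 it was −1.71 (SD 0.10 over 3 spots), which leaves 30.6%. Both levels hold for the main processing only. Over the alternatives the log2 ratio was from −1.73 to −1.14 in Huh7 and from −2.28 to −1.44 in HepG2. The offset draws ratios of dim probes toward 0, and simulated Huh7 probes set to −2 were found at a median of −1.53. A single probe measured THOC5, well above background in both channels of both arrays, and the adjusted p of limma over both lines was 0.060. None of the other measured members of the THO and TREX list passed the 2-fold rule in either line. THOC2, the large scaffold subunit of THO, was at −0.38 in Huh7 and −0.62 in HepG2, with a second probe at 0.19 and −0.02, and THOC1, THOC3, THOC6 and THOC7 were between −0.59 and 0.03. ALYREF, the adaptor that hands mRNA to the export receptor, was at 0.33 in Huh7 and −0.63 in HepG2, while the export receptor NXF1 itself was at 0.09 and 0.14. NCBP1, the larger subunit of the nuclear cap-binding complex, was at −0.76 and −0.61, with a second probe at −0.05 and −0.04, and POLDIP3 was at −0.40 and −0.83, with a second probe at 0.49 and 0.19. Over the 23 members measured in each line, the median was −0.24 in Huh7 and −0.20 in HepG2, and both medians turned positive (0.054 and 0.24) under median centring. The Huh7 median was at percentile 1.81 of random lists of the same size and brightness, and the HepG2 median was at percentile 3.25. THOC5 was the 1 member that passed limma when adjusted over the list alone.

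The second comparison asked which transcripts differed after THOC5 depletion in Huh7 cells. The largest differences were increases. CAB39, a scaffold protein of the LKB1 kinase complex, had a log2 ratio of 4.05 (SD 0.08), and the ubiquitin-like protein UBL3 had 3.85 (SD 0.03). SECISBP2L was at 3.64 (SD 0.08), the membrane protease ADAM10 at 3.60 (SD 0.05), the phosphatase subunit PPP4R2 at 3.58 (SD 0.08), and MBTPS2, the site-2 protease that releases membrane-bound transcription factors, at 3.58 (SD 0.05). The remaining 4 of the 10 highest genes were BROX (3.52), the palmitoyltransferase ZDHHC20 (3.36), the noncanonical poly(A) polymerase TENT4B (3.36) and the kinesin KIF21A (3.34). Second probes of ADAM10 and PPP4R2 were also higher (2.40 and 1.15), whereas second probes were near 0 for CAB39 (−0.11) and ZDHHC20 (0.10).

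The lowest gene in Huh7 was REEP5, which shapes endoplasmic reticulum (ER) tubules, at −2.37 (SD 0.06). It was followed by UACA at −2.36 (SD 0.07), the formaldehyde-detoxifying alcohol dehydrogenase ADH5 at −2.29 (SD 0.05), and the RNA-binding protein RBM12 at −2.13 (SD 0.05). The condensin subunit NCAPG was at −2.09, TPD52 at −2.05, the deubiquitinase USP9X at −2.01, PREPL at −1.93, the splicing regulator HNRNPLL at −1.91 and the ubiquitin-conjugating enzyme UBE2N at −1.90. A second probe of PREPL was at 0.93, on the other side of 0, while second probes of RBM12 (−1.92) and HNRNPLL (−1.08) were also lower. Of 15548 genes measured on the Huh7 array, 681 (4.38%) were lower and 584 (3.76%) were higher by at least 2-fold, so 46.2% of these genes were higher. Median centring in place of intensity-dependent loess gave 372 lower and 951 higher genes, 71.9% higher. Scaling both arrays to the same spread gave 285 lower and 343 higher, and the scanner software's ratios gave 1074 lower and 903 higher.

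The third comparison asked the same of HepG2 cells. CAB39 again had the highest log2 ratio, 4.29 (SD 0.05), followed by ZDHHC20 at 3.76 (SD 0.08), the lysophospholipid acyltransferase LPGAT1 at 3.54 (SD 0.05), BROX at 3.50 (SD 0.11) and TAF13, a subunit of the general transcription factor TFIID, at 3.39 (SD 0.05). UBL3 (3.28), the chondroitin sulfate enzyme CSGALNACT2 (3.26), TENT4B (3.24), PPP4R2 (3.07) and TAB3 (3.05) completed the 10 highest. The other measured probes of CSGALNACT2 were at −0.05 and 2.37, and second probes were at −0.19 for CAB39, 0.03 for ZDHHC20, 0.70 for PPP4R2 and 0.42 for TAB3.

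Of the genes in HepG2, ARG1, the urea cycle enzyme arginase, was lowest at −2.25 (SD 0.05), with a second probe at −1.84. The acute-phase protein haptoglobin, HP, was at −2.04 (SD 0.03), its close paralog HPR, whose signal may not be separate, was at −1.96, and HAMP, the iron-regulating liver hormone hepcidin, was at −1.86. TK1, thymidine kinase of S phase, was at −2.06 (SD 0.02), and SPC25, a kinetochore protein needed for chromosome segregation, was at −2.02 (SD 0.04). ID1, a BMP-responsive inhibitor of differentiation (−1.93), the glutathione peroxidase GPX2 (−1.87) and REEP5 (−1.84) were also among the 10 lowest. In Huh7, HP was at −0.47, HPR at −0.25, HAMP at 0.06 and GPX2 at −0.17; the difference between lines was not tested for these genes. Of 15315 genes measured on the HepG2 array, 333 (2.17%) were lower and 570 (3.72%) were higher, so 63.1% of these genes were higher. Median centring gave 91 lower and 1265 higher (93.3% higher), centring on spike-in RNAs gave 1012 lower and 322 higher (24.1%), and the authors' series matrix values gave 737 lower and 830 higher (53%).

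The fourth comparison asked which transcripts differed alike in both lines. The 12 highest by the smaller of the log2 ratios were CAB39, BROX, ZDHHC20, LPGAT1, UBL3, TENT4B, PPP4R2, TAF13, SECISBP2L, the Cullin adaptor KLHL11, ADAM10 and TAB3, each at 2.88 or more in both lines. Besides THOC5 and REEP5, the 12 lowest held TMED10, a cargo receptor of vesicles between ER and Golgi, at −1.68 in Huh7 and −1.71 in HepG2, with a second probe at −1.16 and −1.21. HSPA5, the main chaperone of the ER, was at −1.71 and −1.44. The histone chaperone NAP1L1 was at −1.86 and −1.65, the phosphatase catalytic subunit PPP1CB at −1.69 and −1.61, the ubiquitin ligase NEDD4L at −1.50 in both lines, and the splicing-related protein U2SURP at −1.82 and −1.39. UBASH3B (−1.88 and −1.39), the kinase RPS6KA3 (−1.53 and −1.38), ANP32A (−1.35 and −1.49) and IGDCC3 (−1.35 and −1.45) were the remaining genes. For PPP1CB, a second probe was at −0.66 and −0.98. A second probe of RPS6KA3 was at 1.5 in Huh7 and 0.22 in HepG2, one of TAB3 was at −0.42 and 0.42, one of CAB39 was at −0.11 and −0.19, one of ZDHHC20 was at 0.10 and 0.03, one of ANP32A was at −0.37 and −0.33, and of the other probes of NEDD4L one was lower (−1.34 and −1.29) and one was at 0.49 and 0.37.

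Among the 14592 genes measured on both arrays, 131 were lower by at least 2-fold in both lines and 319 were higher in both. Independent lists of the same lengths would share 14.2 and 20.5 genes, so the overlaps were 9.23-fold and 15.6-fold above that. The log10 of the one-sided Fisher exact p was −93.4 for the lower and −347 for the higher genes, taken across genes, which are not replicates. Across genes, the log2 ratios of the 2 lines had a Pearson r of 0.664 and a Spearman rho of 0.573, and 70.9% of genes had the same sign. AGR2, a disulfide isomerase of secretory cells, was the 1 gene past 2-fold in opposite directions, at −1.25 in Huh7 and 1.22 in HepG2, where 36.2 genes would be found with independent lists.

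**Figure D1:**
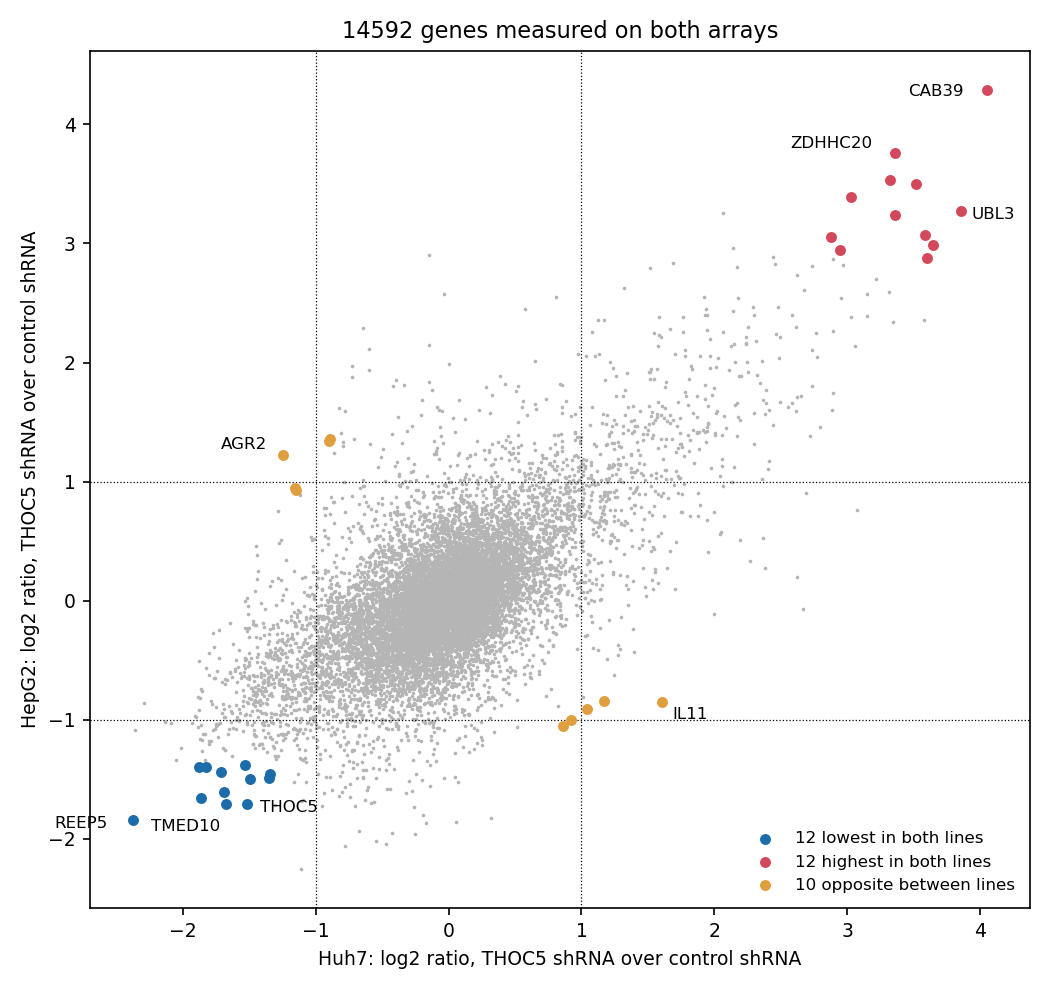
Each point is 1 of 14592 genes measured on both arrays, with its log2 ratio of THOC5 shRNA over control shRNA in Huh7 on the x axis and in HepG2 on the y axis; dotted lines mark the 2-fold rule at −1 and 1. The 12 genes highest in both lines (red) lie at 2.88 or more on both axes, the 12 lowest (blue) include THOC5, and 10 genes (orange) lie on opposite sides of 0.

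With the 2 lines as the replicates, limma with Benjamini-Hochberg adjustment called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.0592; at an unadjusted p under 0.05, 1891 genes were lower and 1534 were higher. That count depended on processing: limma called 136 lower and 325 higher with an intensity trend in the moderation, 838 and 755 on the scanner software's ratios, and 1898 and 646 with spike-in centring. Scaling also moved the split of the shared genes, from 70.9% higher to 97.4% (15 lower and 560 higher) with median centring, 38.8% (354 and 224) with spike-in centring, 59.2% (298 and 433) on the scanner software's ratios and 58.8% (306 and 437) on the series matrix values. Dyes were not swapped, so a dye bias of a probe that is the same on both arrays would also be shared between the lines.

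Probes of one gene did not always give the same direction. Other measured probes of genes past the 2-fold rule had the same sign as the brightest probe in 202 of 464 cases (43.5%) in Huh7 and 209 of 348 (60.1%) in HepG2. In both lines, 10 genes had 1 probe at least 2-fold higher and another at least 2-fold lower, named here after their values were seen: AGPS, BCLAF1, CASK, CAST, OSBPL3, PRRC1, PTP4A1, RUNX1, SSR1 and VMA21. For the calpain inhibitor CAST, the probes were at 1.26 and −1.56 in Huh7 and at 1.07 and −1.14 in HepG2, and for VMA21, an assembly factor of the proton pump, at 2.22 and −1.88 and at 2.29 and −1.06. The values of the named genes are those of 1 probe, and leaving out genes with disagreeing probes lowered the shared higher genes from 319 to 210.

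**Figure D2:**
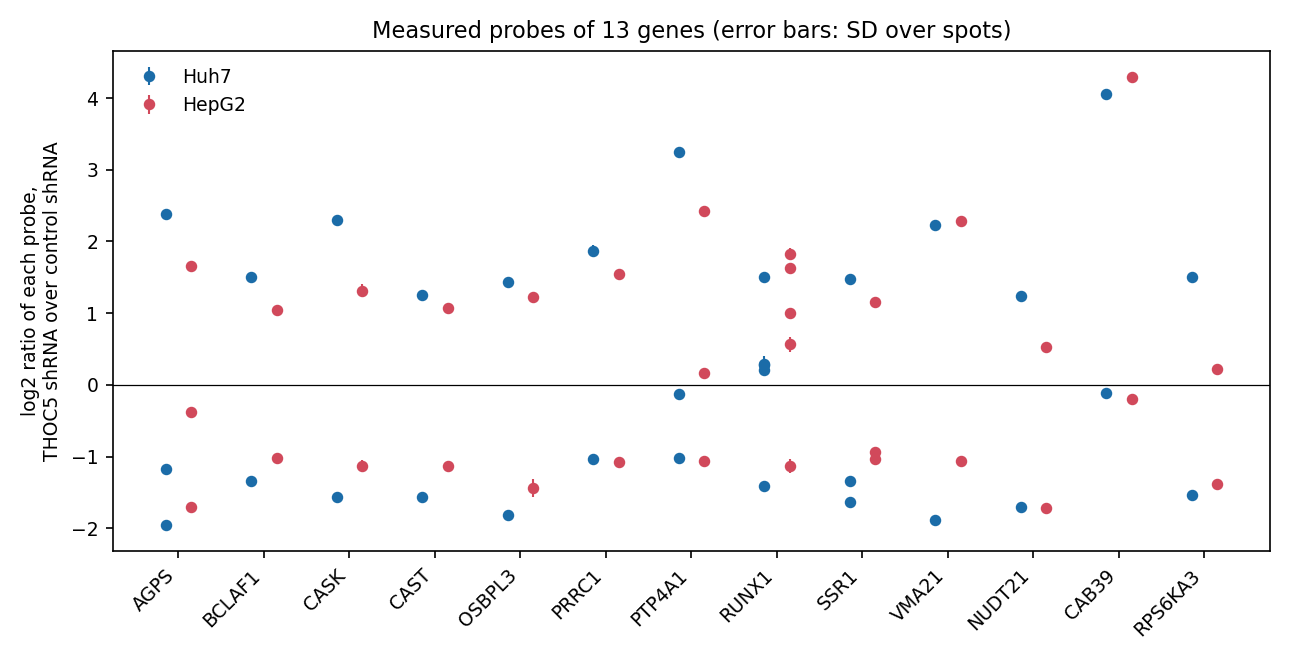
Log2 ratio of THOC5 shRNA over control shRNA (y axis) of each measured probe of 13 genes chosen after their values were seen (x axis), in Huh7 (blue) and HepG2 (red), with error bars for the SD over replicate spots, mostly smaller than the points. The first 10 genes had probes at least 2-fold apart from 0 in opposite directions in both lines.

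Gene lists fixed before the data were examined gave 58 list and line pairs. Of these pairs, 22 had a median outside the central 95% of random lists, 15 below and 7 above. With independent genes and lists 2.9 would be outside. Some genes are in several lists and each list is counted in both lines, so 2.9 is not a strict expectation. Since limma adjusted over all genes called 0 genes on these arrays, no list member could pass it, and that says nothing about the lists. Counts adjusted over the list alone are given with each list that had any. They were not compared with random lists. Over all 14592 genes measured on both arrays, 1891 lower and 1534 higher genes had an unadjusted limma p under 0.05. Members of any list may thus pass when adjusted over the list alone, and these counts are not evidence particular to a list. Here "higher" and "lower" describe these arrays, not tested differences. The medians of the TREX, bile acid, liver cancer marker, fatty acid and immediate early lists in Huh7 and of the liver transcription factor, metallothionein, fatty acid and mesenchymal lists in HepG2 came inside the random range under at least 1 alternative.

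Cell cycle genes were the group with the lowest medians. In HepG2, all 24 measured members of the cell cycle and mitosis list were below 0, 21 of them past the 2-fold rule, with a median of −1.37. The lowest were BIRC5 (−1.72), an inhibitor of apoptosis that also guides chromosome segregation, the mitotic kinase CDK1 (−1.68), its partner cyclin CCNB2 (−1.64) and the spindle protein NUSAP1 (−1.59). In Huh7, all 25 measured members were below 0 but 2 passed the rule, the spindle motor KIF11 (−1.55) and the centromeric histone CENPA (−1.13), and the median was −0.61. Adjusted over the list alone, 20 members were lower over both lines. The DNA replication list was lower too, with a median of −0.51 in Huh7 (4 of 26 past the rule) and −0.90 in HepG2 (10 of 26), and 14 members were lower when adjusted over the list alone. Its members included CDC45 of the replicative helicase (−1.07 and −1.53), the ribonucleotide reductase subunit RRM2 (−1.42 and −1.21), the origin licensing factor CDT1 (−0.75 and −1.35), GINS2 (−0.53 and −1.41) and MCM10 (−1.29 and −0.56). All of these medians lay below every random list in both lines and stayed below 0 under every alternative run.

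Replication-dependent histones went opposite ways in the lines. All 14 measured histone genes were below 0 in Huh7, with a median of −0.48, led by the linker histones H1-4 (−1.54) and H1-2 (−1.45). In HepG2, 13 of 14 were above 0, with a median of 0.64, led by H2BC11 (1.86), H2AC6 (1.81) and H2BC5 (1.62), while H4C3 was at −1.69. Histone genes are near-identical in sequence, so the values of single members are uncertain. Both medians kept their sign under every alternative, 0 members passed limma adjusted over the list alone, and the difference between lines was not tested.

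**Figure D3:**
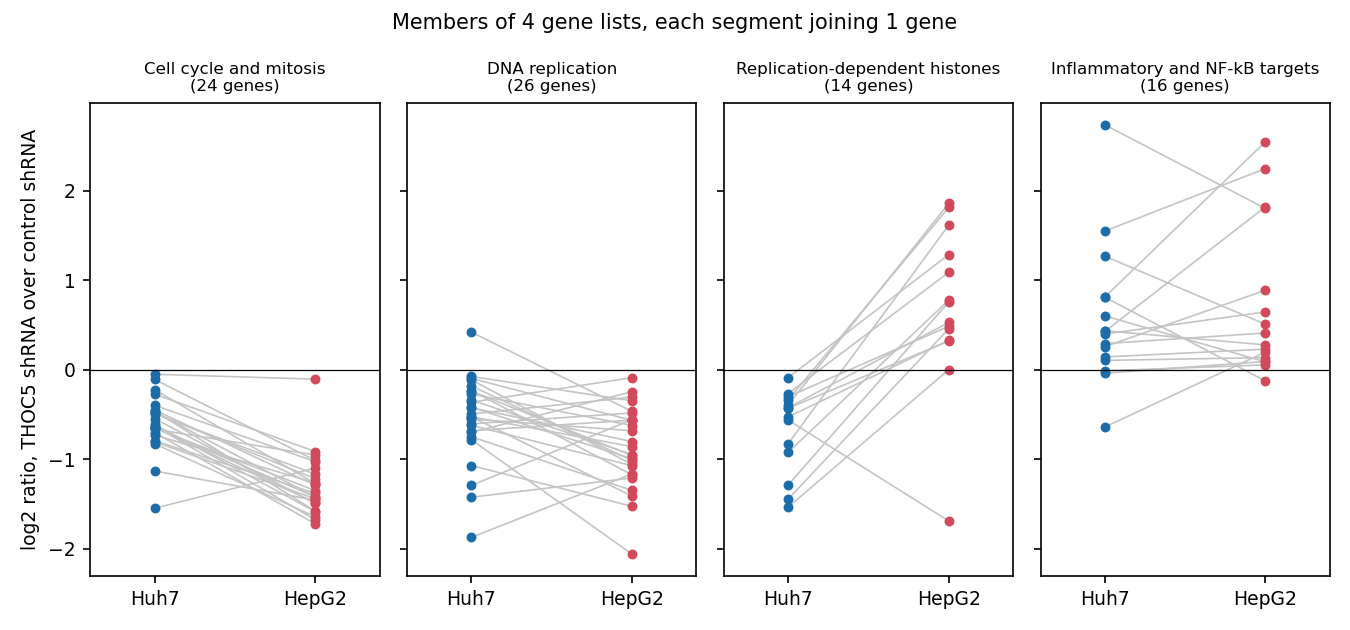
Log2 ratios of THOC5 shRNA over control shRNA (y axis) for the members of 4 gene lists measured on both arrays, with Huh7 in blue, HepG2 in red and a grey segment joining the values of each gene. Most cell cycle genes were lower in HepG2 than in Huh7, and 13 of 14 histone genes were below 0 in Huh7 and above 0 in HepG2.

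Secreted liver proteins, the main products of hepatocytes, had medians of −0.28 in Huh7 and −0.42 in HepG2, the latter turning to 0.058 under median centring. In Huh7, 3 of 30 passed the rule: the lipoprotein component APOA2 (−1.40) and the acute-phase glycoproteins ORM1 (−1.12) and ORM2 (−1.10), paralogs whose probes may not separate them. In HepG2, 4 passed, HP, ORM2 (−1.11), the fibrinogen chain FGA (−1.10) and ORM1 (−1.08), and 3 list members were lower when adjusted over the list alone. Serum albumin, ALB, was at 0.20 and 0.25. Liver transcription factors had a median of −0.11 in Huh7, within the random range and turning to 0.18 under median centring, and −0.29 in HepG2, at percentile 0.42. The bile acid receptor NR1H4 (−1.46) and CEBPA (−1.56), which drives hepatocyte differentiation, were lower in HepG2, at −0.25 and −0.14 in Huh7. PROX1, a regulator of liver and lymphatic development, was at 1.94 and 1.42, and NR0B2, a repressor of bile acid synthesis, was at −1.07 and −0.63. HNF4G was not well above background in 1 channel, and was at least 1.58-fold higher in Huh7 and 2.06-fold higher in HepG2. Adjusted over the list alone, 2 of these factors were lower and 3 higher.

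Genes of bile acid, drug and urea cycle metabolism had a median of 0.23 in Huh7, at percentile 99.2, and 0.00 in HepG2, at percentile 47.0. The bile canalicular pump ABCC2 (1.25 and 1.51) and the drug-metabolising enzyme CYP3A5 (1.31 and 1.4, with a second probe at 0.34 and 0.56) were higher in both lines, and ARG1 was lower in both (−1.11 and −2.25); adjusted over the list alone, 1 gene was lower and 2 were higher. Liver cancer markers had a median of −0.31 in Huh7 and −0.19 in HepG2, the latter within the random range and turning to 0.17 under median centring. The adhesion receptor CD44 (−1.44), the Golgi protein GOLM1 (−1.30) and the growth factor IGF2 (−1.06) were lower and osteopontin, SPP1 (1.28), was higher in Huh7. In HepG2 these were at 0.18, −0.19, −0.67 and −0.45. Second probes were at −1.05 in Huh7 and 0.10 in HepG2 for GOLM1, and at −0.41 in both lines for IGF2. TERT, the catalytic subunit of telomerase, was at −0.92 in Huh7 and −1.03 in HepG2, and 1 marker was lower when adjusted over the list alone.

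Inflammatory and NF-kB targets were higher, with a median of 0.43 over 19 genes in Huh7 and 0.34 over 16 in HepG2. The mitochondrial superoxide dismutase SOD2 was at 2.73 and 1.80, TNFAIP3, a feedback inhibitor of NF-kB, at 1.55 and 2.25, and BIRC3 at 0.81 and 2.55. The adhesion molecule ICAM1 (1.27) was the third gene past the rule in Huh7, and the chemokine CCL20 (1.82) was the fourth in HepG2. Adjusted over the list alone, 2 members were higher. Metallothioneins, small metal-binding proteins, had medians of 0.45 and 0.32; 0 of 11 passed the rule upward in either line, MT1G was at −1.04 in HepG2, 0 passed limma adjusted over the list alone, and the family's probes may share signal. Immediate early genes had a median of −0.20 in Huh7, at percentile 2.31 and turning to 0.038 under median centring, and 0.42 in HepG2, above all random lists. ATF3 was at 1.52 and 2.80, with its other probes between 0.13 and 1.02, EGR1 at −1.16 and 0.94, FOSB at 0.50 and 1.20, and 3 members were higher when adjusted over the list alone.

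Lipid genes were lower in part. Fatty acid synthesis genes had medians of −0.40 and −0.36, the HepG2 value turning to 0.079 under median centring; GPAM, which starts triglyceride synthesis, was at −1.05 and −1.09 and the carboxylase ACACB at −0.92 and −0.77, while ACLY, which makes cytosolic acetyl-CoA, was at 1.71 and 1.09. Adjusted over the list alone, 6 of these genes were lower and 1 was higher. Cholesterol genes had a median of −0.27 in Huh7 and −0.11 in HepG2, the latter turning to 0.32 under median centring; 0 passed limma adjusted over the list alone. Mesenchymal and fibroblast genes had a median of −0.16 in Huh7, turning to 0.15 under median centring, and −0.38 in HepG2, at percentile 0.18. SPARC was at −0.66 and −0.93. ZEB1, a repressor of epithelial genes, was at −1.01 and −0.42, with a second probe at −0.42 and 0.10. The collagen COL1A1 was not well above background in 1 channel and at least 2.14-fold lower in HepG2.

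**Figure D4:**
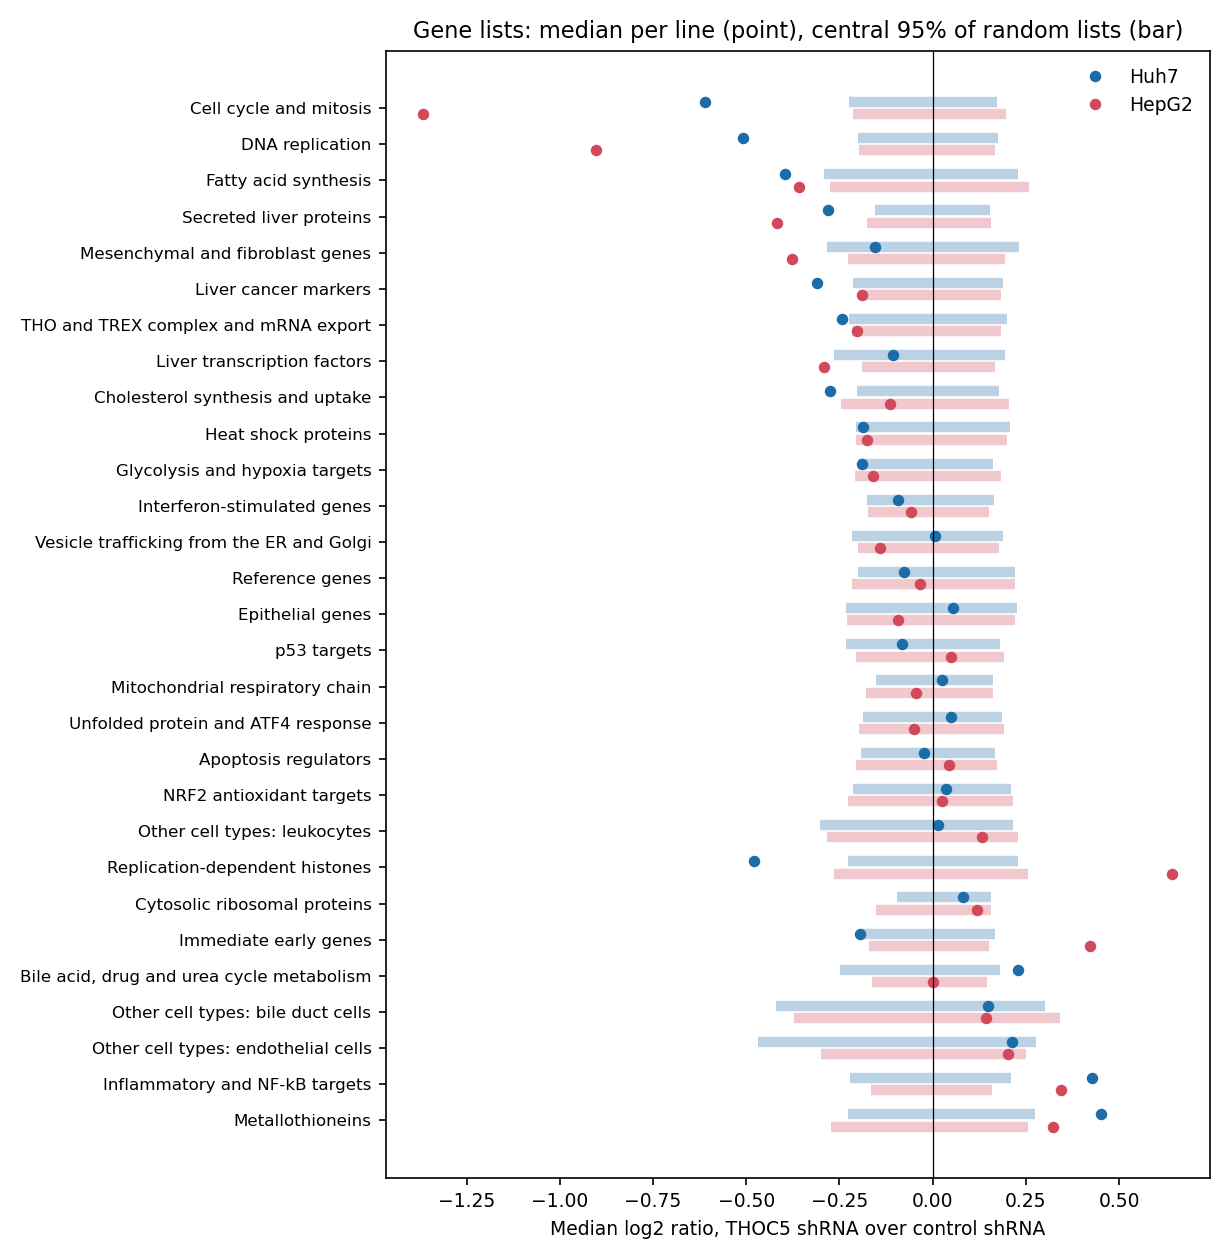
Median log2 ratio of THOC5 shRNA over control shRNA (x axis) of each gene list (y axis) in Huh7 (blue points) and HepG2 (red points), with bars for the central 95% of medians of random lists of the same size and brightness. The cell cycle list lies at −0.61 in Huh7 and −1.37 in HepG2, and the histone list at −0.48 and 0.64.

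The medians of the remaining lists lay within the random range in both lines under the main processing. Under at least 1 alternative, those of p53 targets, apoptosis regulators and ribosomal proteins in HepG2, of endothelial markers in both lines and of glycolysis and hypoxia targets in Huh7 left it, as did liver cancer markers in HepG2. Members of the unfolded protein and ATF4 response list split: besides HSPA5, PDIA4 was at −1.05 in HepG2, while DDIT3 (1.06 and 1.47), PPP1R15A (1.03 and 1.18) and ATF3, all induced through ATF4, were higher, and 1 member was lower and 4 higher when adjusted over the list alone (medians 0.05 and −0.05). Vesicle trafficking genes split in the same manner. TMED10, the coatomer subunit COPA (−1.10 and −0.76) and SEC24A (−1.09 and −0.84) were below 0, and SAR1A (1.74 and 1.31) and MCFD2 (1.43 and 1.26) above, with 4 lower and 4 higher adjusted over the list alone and medians of 0.01 and −0.14; second probes of SEC24A, SAR1A and MCFD2 lay on the other side of 0. The study's own interest in vesicle proteins was known when this list was fixed, so it is not independent evidence. Among NRF2 antioxidant targets (medians 0.04 and 0.03), TXNRD1 was at 1.0 and 1.04, GCLC at −1.15 and −0.63, and HMOX1 at 0.16 and 1.22. In Huh7, 1 lower and 1 higher member passed the 2-fold rule. The higher one was GSR (1.17, with a second probe at −0.82), while TXNRD1 stayed just inside the rule. In HepG2, 1 lower and 2 higher members passed it. Adjusted over the list alone, 1 was lower and 3 were higher. The tight junction gene OCLN (1.95 and 1.63, with a second probe at 1.76 and 1.37) was the 1 epithelial gene that passed adjusted over the list alone, in a list with medians of 0.05 and −0.09.

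For p53 targets (medians −0.08 and 0.05), CDKN1A, the p21 inhibitor of the cell cycle, was at 1.53 and the death receptor FAS at 1.42 in HepG2; in Huh7 both were not well above background in 1 channel. GADD45A was at 0.98 and 1.37. Among apoptosis regulators (medians −0.02 and 0.04), BCL2L11, which triggers mitochondrial apoptosis, was at −1.46 in Huh7, turning to 0.11 as the median over its probes. In Huh7, BMF was at 1.12, with a second probe at 0.58, and HRK was at 1.21. TMBIM6 was at 0.87 in Huh7 and 0.80 in HepG2, with a second probe at −0.35 and −0.81. TMBIM4, included because of the study's known interest and so not independent evidence, was at 0.06 and 0.40. Interferon-stimulated genes had medians of −0.09 and −0.06. In Huh7, 1 member was past the 2-fold rule downward, the RNA sensor RIGI (−1.13), and 2 were past it upward. In HepG2, 1 was past it downward, IFIT1 (−1.29), and 0 upward. Medians were −0.19 and −0.18 for heat shock proteins (HSPH1 at −1.29 in Huh7 and −0.48 in HepG2, with a second probe at 0.27 and 1.08), −0.19 and −0.16 for glycolysis and hypoxia targets (PDK1 at −1.39 in Huh7 and VEGFA at 1.25 in HepG2), 0.08 and 0.12 for ribosomal proteins, and 0.02 and −0.04 for the respiratory chain. Marker lists of other cell types had medians of 0.15 and 0.14 (bile duct), 0.21 and 0.20 (endothelium) and 0.01 and 0.13 (leukocytes). Reference genes had medians of −0.08 and −0.03, with GAPDH at −0.31 and −0.32. The within-range medians of all these remaining lists changed sign under at least 1 alternative, apart from the bile duct and endothelial markers in Huh7. None of the lists in this paragraph had a member that passed limma adjusted over the list alone.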

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

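The comparison of direction between the lines was fixed before the data were examined, and the 1.5-fold limit used here was chosen after the results were seen. Results are listed where a named gene was past 1.5-fold in opposite directions in the 2 lines, or where a list's median lay outside the random range on opposite sides. With 1 array per line, the difference between lines was not tested for any of them, and no explanation for them was tested.

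Several histone genes were lower in Huh7 and higher in HepG2. H2BC12 was at −1.29 in Huh7 and 0.76 in HepG2, H2AC8 at −0.92 and 0.78, H2BC3 at −0.90 and 1.35, H2BC18 at −0.90 and 1.36, and H2BC5 at −0.83 and 1.62. The median of the replication-dependent histone list was −0.48 in Huh7 and 0.64 in HepG2. A second probe of H2BC12 was at −0.79 and 1.72.

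The median of the immediate early genes was −0.20 in Huh7 and 0.42 in HepG2. The Huh7 value lay at the edge of the random range (percentile 2.31), with 12 of 23 members below 0. It turned to 0.038 under median centring and to 0.062 without a filter on dim probes. A member of the list, EGR1, a growth-factor-induced transcription factor, was at −1.16 and 0.94. AGR2, a disulfide isomerase of secretory cells, was at −1.25 and 1.22, and GLIPR1 at −1.15 and 0.93. In the other direction, the cytokine IL11 was at 1.61 in Huh7 and −0.85 in HepG2, DOK6 at 1.17 and −0.84, the retinaldehyde dehydrogenase ALDH1A1 at 1.04 and −0.91, the collagen crosslinking enzyme LOX at 0.92 and −1.0, the FGF coreceptor KLB at 0.86 and −1.05, and the metallothionein MT1F at 0.77 and −0.74. A second probe of ALDH1A1 was at 0.98 and −1.22, and a second probe of KLB was at −0.63 and −1.41.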

How the results depend on the processing

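Spike-in centring and leaving out genes with disagreeing probes were chosen after the data were seen; the other alternatives were planned. Below, pairs are lower and higher genes. THOC5 stayed lower and past the 2-fold rule in both lines under every alternative, from −1.73 to −1.14 in Huh7 and from −2.28 to −1.44 in HepG2. Over the alternatives, results for named genes in a line kept sign and side of the 2-fold rule 5217 times. They changed sign while inside it 88 times, came inside it 124 times, passed it 162 times and reversed from past it once. Filters do not alter a named gene's value, so some of the 5217 could not differ. These were 466 each for no filter on dim probes, both channels well above background, and disagreeing probes left out. List medians kept sign and side of the random range 616 times, changed sign while inside it 49 times and came inside it 18 times. They left it 8 times and reversed from outside it 5 times. Spike-in centring and scaling to the same spread could not move a median across the random range, which moves with the array. Medians left it upward for ribosomal proteins (0.83) and endothelial markers (0.50) in HepG2 under median centring, for endothelial markers in both lines without a filter on dim probes (0.18 in both), and for p53 targets (0.21) and apoptosis regulators (0.16) in HepG2 with the median over all probes. They left it downward for liver cancer markers in HepG2 on the scanner software's ratios (−0.27) and for glycolysis and hypoxia targets in Huh7 without the filter (−0.19). Where a value moved, the cause was not tested, except that the size rule and probe choices act by construction.

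Median centring moved the median of all genes from 0.02 to 0.19 in Huh7 and from 0.01 to 0.23 in HepG2, and spike-in centring moved it to −0.05 and −0.31. Median centring gave 372 and 951 genes in Huh7, 91 and 1265 in HepG2, 15 and 560 in both lines, 71 and 868 by limma, and THOC5 at −1.23 and −1.44. Of the 319 genes shared upward, all 319 were also shared then, and 15 of the 131 shared downward. Of the list medians outside the random range, it reversed mRNA export in Huh7 (0.054), secreted liver proteins in HepG2 (0.058), fatty acid synthesis in HepG2 (0.079) and immediate early genes in Huh7 (0.038); relative to the shifted median of all genes these stayed lower. It also changed the sign of 19 list medians inside the range, such as heat shock proteins in HepG2 (0.34) and mRNA export in HepG2 (0.24), and spike-in centring of 14. Spike-in centring gave 1012 and 322 genes in HepG2, 354 shared lower genes, 2 opposite genes, 1898 and 646 by limma, and THOC5 at −1.59 and −2.03. Scaling both arrays to the same spread gave 285 and 343 genes in Huh7, 798 and 973 in HepG2, and THOC5 at −1.14 and −2.28.

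The scanner software's ratios gave 1074 and 903 genes in Huh7, 711 lower genes in HepG2, 298 shared lower and 12 opposite genes, 838 and 755 by limma, and THOC5 at −1.73 and −2.25. The series matrix values gave 1075 and 911 genes in Huh7, 737 lower genes in HepG2, 306 shared lower and 14 opposite genes, 1000 and 856 by limma, and THOC5 at −1.73 and −2.23. An offset of 10 gave 4 opposite genes, 419 and 571 by limma, and THOC5 at −1.62 and −1.93. Without background correction limma called 4 and 95 genes, with both channels required well above background 10 and 124, and with an intensity trend 136 and 325. Without a filter on dim probes the correlation between lines was 0.630, and the immediate early median in Huh7 reversed to 0.062.

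Taking the median over all probes of a gene gave 199 shared higher genes, 3 opposite genes and a correlation of 0.629, and reversed BCL2L11 in Huh7 (0.11). Leaving out genes with disagreeing probes gave 210 shared higher genes and a correlation of 0.641. A 1.5-fold rule gave 1865 and 1330 genes in Huh7, 1403 and 1452 in HepG2, 712 and 740 in both lines, and 65 opposite genes. A 3-fold rule gave 90 and 233 in Huh7, 33 and 199 in HepG2, 4 and 115 in both lines, and 0 opposite genes. Each array pairs both RNAs of a line, so limma over both lines is a paired test; a replicate block was not fitted, as the labels carry no replicate numbers. The slide as a block was not run, since both arrays lie on one slide. Signal over background limits dim genes, whose ratios the offset draws toward 0.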

Other observations

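The tests of RNA degradation, of an equal dye bias and of shuffled probes were chosen after the results they measure were seen, as were the genes named here with their probe values; the 3′ end test and the normalization test were set before their results were seen. For the shuffles, the counts of genes with opposite probes had been seen and the shuffled counts had not, and the rule for reading the HepG2 count was completed after both.

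Some factors that cut and polyadenylate the 3′ ends of mRNA are given here; they were picked after their values were seen, from no fixed list, and went both ways. CPSF6, a subunit of cleavage factor I, was at 1.68 in Huh7 and 1.36 in HepG2, and the poly(A) polymerase PAPOLA was at 1.52 and 1.06. PCF11, which links cleavage to the end of transcription, was at −1.23 and −1.12, and CPSF7 was at 0.41 and 0.24. NUDT21, the small subunit of cleavage factor I, had one probe at 1.24 and 0.53 and another at −1.70 and −1.72.

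NUDT21 was not alone in this. Among 3239 genes with at least 2 measured probes, 765 (23.6%) in Huh7 and 551 (17%) in HepG2 had probes at least 2-fold apart, and across genes the log2 ratios of the brightest and the second probe had a Pearson r of −0.08 and 0.13. The difference between these probes was shared by the lines, with an r across genes of 0.863. In both lines, 10 genes had 1 probe at least 2-fold higher and another at least 2-fold lower, among them CAST and VMA21.

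Opposite probes within a gene have at least 3 candidate explanations. In Huh7, 85 genes had opposite probes, where 1000 shuffles of probes among genes of like brightness gave 21 to 49. That argues against a bias that acts on each probe independently as the whole cause there. In HepG2, the 11 genes lay within the 1 to 25 of the shuffles, so that count does not decide. Of these 11 genes, 10 also had opposite probes in Huh7. The probe differences were smaller in HepG2, with a slope of 0.69 on those in Huh7, which leaves fewer genes to count. Degradation of 1 of the RNAs stays open. In Huh7, the 5′ minus 3′ control probes differed by −0.42 for GAPDH and −0.01 for PGK1 (mean −0.22). In HepG2 they differed by −0.41 and −0.46. Each control probe had 1 or 2 spots, and the PGK1 value in Huh7 rests on 1 spot per end. These differences are under the 2-fold gap of the pattern, but they come from 2 genes outside it, and in HepG2 both were lower at the 5′ end. An altered choice of transcript 3′ ends after THOC5 depletion is a hypothesis that also stays open: of 9 genes known to shift their poly(A) site with cleavage factor I, only 2 had several measured probes, too few for the test to decide (one-sided Fisher exact p = 0.417 across genes, which are not replicates). The positions of the probes on their transcripts were not used here, and off-target effects of the hairpin, shared between the lines, were not tested.

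The lower cell cycle genes in HepG2 were weighed against technical causes. Over 12 alternatives, the median of the list stayed between −1.82 and −1.01, below all random lists each time. Only some of these alternatives change normalization or centring, and the others change background, filters, spots or probes. When a whole array is shifted or rescaled, the random lists move too, so that place among them could not change. The median itself stayed at −1.01 or lower with median centring, spike-in centring, scaling to the same spread and the scanner software's ratios. That argues against these choices as the whole cause. A dye bias of the same size on both arrays would give equal values. The 24 genes were lower in HepG2 than in Huh7 by a median of −0.76, with 23 of 24 lower. The SE of 0.09 and the SD of 0.36 are across genes, which are not replicates, and each line has 1 array. On these 2 arrays, an equal dye bias does not account for the whole pattern. A smaller share of dividing cells in the THOC5 shRNA culture of HepG2 may underlie these values and stays a hypothesis, since no measure of division and no second culture was analysed here. In the same culture, the DNA replication list had a median of −0.90, with 26 of 26 below 0. The replication-dependent histones had a median of 0.64 (percentile 99.98 of random lists), with 13 of 14 above 0. What a change in the share of dividing cells would do to these histone values was not tested. Neither list decides between this hypothesis and other causes. A difference in RNA quality, the loss of THOC5 and another effect of the hairpin were not tested as causes of the lower cell cycle values.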
